A study of Mus musculus with 24 samples.

How the data were processed

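H3K4m3-Seq, sequencing of chromatin immunoprecipitated with an antibody against histone H3 trimethylated at lysine 4, was carried out on mouse brain, heart, kidney and liver that had been either flash frozen or formalin-fixed and paraffin-embedded (FFPE). The labels describe 24 samples, 12 H3K4m3 and 12 input libraries, with 4 frozen and 8 FFPE samples among the H3K4m3 libraries. The values used here came from a table of 8 columns, 1 for each organ and preservation type. The columns name no antibody or replicate. They were taken as H3K4m3 because the table and the series are titled so. Whether an FFPE column holds 1 of the 2 FFPE libraries of its organ or both merged is not given in the sources used here. Each column is called a library below, with 2 libraries per organ and 4 per preservation type.

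The authors deposited normalized log2 values per gene. Alignment with Bowtie2, counting per gene with featureCounts, limma and the mouse build mm10 are named per the submitters' processing notes. Tool versions, and the part of each gene in which reads were counted, are not given in the sources used here. The deposited log2 values had the form log2 of (reads + 0.5) over a scaled library size, and whole read numbers were recovered from them to within 0.001 for 100% of values in every library. Per the labels' protocols, frozen and FFPE tissue were brought to sheared chromatin by different procedures. The labels name 2 families of library kits without saying which was used for which sample, so preservation, tissue preparation and any kit difference cannot be told apart.

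The recovered depth was 2513301 reads in frozen brain, 1792394 in frozen heart, 2267190 in frozen kidney and 2976029 in frozen liver. It was 4811825 in FFPE brain, 3388631 in FFPE heart, 5275085 in FFPE kidney and 3800135 in FFPE liver. A gene needs 100 reads for a counting error of 10 percent. A count of 0 allows up to 3 reads, which corresponded to between 0.537 CPM (the deposited scale without the log) in FFPE kidney and 1.69 in frozen heart. Counting intervals and these limits cover counting error only, since amplified reads are not independent molecules.

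The table held 27179 genes, of which 25680 had a mean log2 value of at least 0 and were tested. Symbols were missing for 1275 genes, and 25275 gene IDs matched a RefSeq gene table of the GRCm38 assembly, the assembly that mm10 denotes. Coordinates are from that table.

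Differences were tested with limma 3.58.1 (linear model, empirical Bayes with an intensity trend) in R 4.3.3 on the deposited log2 values, with organ and preservation in 1 model of 8 libraries and 3 residual degrees of freedom. The 5 comparisons were each organ against the mean of the other 3, and FFPE against frozen. An organ can therefore be lower at a gene only because 1 of the other organs is high. Adjusted p-values are Benjamini-Hochberg values over all tested genes, and a gene is said to pass when its adjusted p is under 0.05. The labels do not say that libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical. With 1 library per organ and preservation type, the model takes the preservation difference as equal in all organs, and every departure from that counts as spread.

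The comparisons, the low-value filter, 20 gene lists, the rule for named genes and most alternative analyses were chosen before the data were examined. The lists were neuron and glia markers, heart sarcomere genes, heart regulators with calcium handling and secreted peptides, kidney proximal tubule genes, kidney loop, distal tubule and collecting duct genes, podocyte genes with kidney transcription factors, liver plasma protein genes, liver enzymes and transporters, liver transcription factors, immune, endothelial, fibroblast and smooth muscle markers, red blood cell genes, housekeeping genes, immediate early genes, Hox genes, cytoplasmic ribosomal protein genes, olfactory and vomeronasal receptor genes, and Y-linked genes. Named genes were those with the largest differences among genes that passed and whose libraries of an organ all lay on the same side of the libraries of the other organs. This part of the rule had been written for more libraries and was applied to the 2 libraries of an organ and the 6 others. For FFPE against frozen, the sign had to be the same in all 4 organs. To these came the list members with the smallest p in each comparison and the member that moved most against its list. Some genes that the rule gives are not reported here. Lists were tested with limma's camera at a preset correlation of 0.01 over 100 pairs of list and comparison, of which 58 passed. With a correlation estimated from the data, 0 of the 100 pairs passed, with 12 at an unadjusted p under 0.05. In that setting camera takes its p-values from the 3 residual degrees of freedom, so hardly any pair could pass after adjustment. With the preset correlation they come from the number of genes instead. The loss of calls given below for each list is therefore not due to the correlation alone.

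Reads were simulated from the library sizes and the means per preservation type, equal in all organs, with the same dispersion of 0.02 for every gene. For FFPE against frozen the means were also equal in both preservation types. The dispersion was estimated from the residual spread of genes with a mean over 100 reads. Changes were put only into genes whose mean lay well above the low-value filter. All changes of 4-fold were recovered in each comparison. Changes of 2-fold were recovered in 76% of cases for brain, 80% for heart, 80% for kidney, 74% for liver and 94% for FFPE against frozen, with 100 changed genes of each size. False calls numbered 13 of 189 for brain, 21 of 201 for heart, 12 of 192 for kidney, 16 of 190 for liver and 6 of 200 for FFPE. Preservation differences that depend on the organ were simulated only as this uniform spread, so these rates need not hold for the real libraries.

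Alternatives chosen before the data were examined were no low-value filter, a mean log2 value of at least 2, quantile normalization, an added threshold of 1 on the absolute log2 fold change, and leaving out each library. Added after the data were seen were limma precision weights from the recovered reads, scaling to the reads outside the mitochondrial genome and the ribosomal RNA precursor gene Rn45s, and libraries stretched to common receptor and housekeeping medians. Correlations, exact permutation tests, thinning of reads and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The input libraries and the separate FFPE replicates were not analysed here, so 6 planned comparisons were not run: the interaction of organ and preservation, 3 comparisons of H3K4m3 with input, the interaction of antibody and preservation, and the comparison of dates.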

Results

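Trimethylation of histone H3 at lysine 4 marks the promoters of active and poised genes. It was profiled in brain, heart, kidney and liver of mice, each preserved by freezing or as FFPE tissue. The values used here held 1 column, called a library, for each of the 8 combinations. Depth ranged from 1792394 reads in frozen heart to 5275085 reads in FFPE kidney, and each FFPE library was deeper than the frozen library of its organ. Whether an FFPE column merges both FFPE samples of its organ is not given, so the greater depth may come from merging. The design names correlation and differential analysis of the preservation types over the 4 organs as its aims. The 5 comparisons below therefore ask which genes set each organ apart, and which differ between FFPE and frozen tissue.

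Brain carried more H3K4m3 than the mean of the other organs at neuronal genes, and less than that mean at Hox genes, endothelial markers and liver regulators. Mir124a-1hg, host gene of a microRNA abundant in neurons (gene ID 268755, GRCm38 chromosome 14, 64588115 to 64593961), was 15.7-fold higher, a log2 difference of 3.97 ± 0.28 (SE, 2 brain and 6 other libraries, adjusted p = 3.25e-06). Slitrk1, a synaptic adhesion protein of neurons (gene ID 76965, chromosome 14, 108909988 to 108914239), was 12.0-fold higher, at 3.59 ± 0.36 with an adjusted p of 3.17e-05. Nap1l2, a neuronal nucleosome assembly factor, was 14.4-fold higher and Ttc9b 13.1-fold higher. Among the genes lowest in brain were Hox genes of cluster B, which pattern the body axis behind the forebrain: Hoxb5 differed by -3.45 ± 0.28, Hoxb4 (gene ID 15412, chromosome 11, 96318267 to 96321638) by -3.36 ± 0.26 and Hoxb2 by -3.29 ± 0.26.

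Of the 20 neuron markers, 18 passed as higher in brain, 19 adjusted over the list alone, with a median of 1.61. The glutamate receptor subunits Grin1 and Gria2 were 5.52-fold and 4.49-fold higher. The list's camera call (adjusted p = 1.28e-18) was lost at an adjusted p = 0.331 with an estimated correlation. Glia markers were higher for 6 of 16 members, 7 adjusted over the list alone, with a median of 0.74, led by the myelin gene Mbp at 3.1-fold and the astrocyte gene Aldoc at 2.86-fold (adjusted p = 0.565 with an estimated correlation). Endothelial markers were lower for 8 of 12 members, 9 adjusted over the list alone, with a median of -1.03. Robo4 differed by -1.78 ± 0.23 and the angiogenic factor Egfl7 by -1.77 ± 0.23 (adjusted p = 0.331 with an estimated correlation). Hox genes were lower for 23 of 39 members, 24 adjusted over the list alone, with a median of -1.35 (adjusted p = 0.331 with an estimated correlation). Liver transcription factors were lower for 9 of 12 members, 11 adjusted over the list alone, with a median of -1.46, among them the pioneer factor Foxa2 at -2.26 ± 0.38 and Cebpa at -1.44 ± 0.18 (adjusted p = 0.52 with an estimated correlation). Each of these lower lists was high in 1 of the organs that brain was set against. The medians were 1.11 for endothelial markers in heart, 2.20 for Hox genes in kidney and 2.23 for liver transcription factors in liver. Part of each lower value in brain may come from that organ. Lhx1, on the kidney list but also a neural transcription factor, was 3.22-fold higher in brain. Coro1a, on the immune list, was 3.16-fold higher. Among immediate early genes, 2 of 19 were higher and 3 lower, 4 and 5 adjusted over the list alone. Zfp36, which destabilises inflammatory messenger RNAs, differed by -2.35 ± 0.28, and Klf4 by -1.14 ± 0.17.

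In all, 2583 genes passed in brain, 1420 higher and 1163 lower. For 1914 of these the brain libraries did not overlap the others. Of all tested genes, 12.2% had no overlap, against 7.14% for exchangeable libraries, which these are not. The count was 326 without frozen brain, 1598 without FFPE brain and 4291 without FFPE liver. Without frozen brain, Lhx1, Coro1a, Foxa2, Klf4 and Aldoc no longer passed.

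Heart was set apart by contractile genes, cardiac transcription factors and endothelial markers. Kcna5, a potassium channel of atrial muscle (gene ID 16493, chromosome 6, 126532551 to 126535555), was 8.35-fold higher, at 3.06 ± 0.28 (SE, 2 heart and 6 other libraries, adjusted p = 0.000181). Hand2, a transcription factor of heart development (gene ID 15111, chromosome 8, 57320983 to 57324517), was 7.97-fold higher, at 2.99 ± 0.37. Nkx2-5, an early regulator of cardiac fate, was 6.53-fold higher and Actc1, cardiac actin (gene ID 11464, chromosome 2, 114047282 to 114052875), 6.48-fold higher. Mhrt, a cardiac noncoding RNA gene, was 11.0-fold higher, but it overlaps Myh7, so reads of the pair could not be separated. The muscle genes Cox6a2, Tnni3 and Pgam2 were 10.3-fold, 6.13-fold and 6.1-fold higher.

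Heart sarcomere genes were higher for 9 of 17 members, 16 adjusted over the list alone, with a median of 1.61. Myh7 was 4.54-fold higher, and the Z-disc gene Ldb3 2.23-fold higher (adjusted p = 0.331 with an estimated correlation). Heart regulators and peptides were higher for 6 of 17 members, 12 adjusted over the list alone, with a median of 1.32. The cardiac transcription factors Tbx20 and Gata4 were 4.25-fold and 3.37-fold higher (adjusted p = 0.331 with an estimated correlation). Endothelial markers were higher for 9 of 12 members, 10 adjusted over the list alone, with a median of 1.11. They included Pecam1 at 3.07-fold, the growth factor receptor Kdr at 2.87-fold and Eng at 2.36-fold (adjusted p = 0.331 with an estimated correlation). Fibroblast and smooth muscle markers were higher for 2 of 12 members, 7 adjusted over the list alone, with a median of 0.70 (adjusted p = 0.52 with an estimated correlation). Both were matrix genes, Lum at 3.21-fold and Dcn at 3.04-fold. Wt1, a podocyte regulator that is also active in the epicardium, was 4.51-fold higher, and Klf4 3.29-fold higher. Immediate early genes were higher for 2 of 19 members, 5 adjusted over the list alone, with a median of 0.32 (adjusted p = 0.331 with an estimated correlation). Some olfactory receptor genes near 0 reads passed as lower: Olfr1048 had 0 reads in heart and 67 elsewhere, at least 5.04-fold lower, and Olfr485 had 0 and 47 reads, at least 3.54-fold lower, with 3 reads as the limit over the group. Neither passed after quantile normalization.

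In heart, 661 genes passed, 442 higher and 219 lower, and the 2 libraries did not overlap the others for 433 of them. No overlap was found for 6.58% of tested genes, against 7.14% for exchangeable libraries, which these are not, so the value does not show a share below chance. The count was 2 without frozen heart, with 1810 at an unadjusted p under 0.05, and none of the heart genes named above then passed with limma. It was 213 without FFPE heart, 256 without FFPE brain, 350 without frozen brain, 250 without FFPE kidney, 185 without frozen kidney, 2097 without FFPE liver and 1285 without frozen liver. After quantile normalization the count was 1382, with 837 higher and 545 lower. With precision weights 382 genes were higher and 35 lower, so that the share of higher calls was 91.6% in place of 66.9%.

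Kidney was distinguished by Hox genes and by genes of the tubule. Hoxb8 (gene ID 15416, chromosome 11, 96279401 to 96285325) was 10.1-fold higher, at 3.34 ± 0.28 (SE, 2 kidney and 6 other libraries, adjusted p = 0.000151). Hoxa9 was 16.8-fold and Hoxb6 12.5-fold higher. Cldn8, a tight junction protein of the distal nephron (gene ID 54420, chromosome 16, 88560826 to 88563183), was 12.2-fold higher, at 3.61 ± 0.36. Kap, an androgen-regulated gene of the proximal tubule (gene ID 16483, chromosome 6, 133849855 to 133853667), was 20.4-fold higher, at 4.35 ± 0.88 with an adjusted p of 0.0284. It did not pass without the low-value filter or with precision weights.

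**Figure D1:**
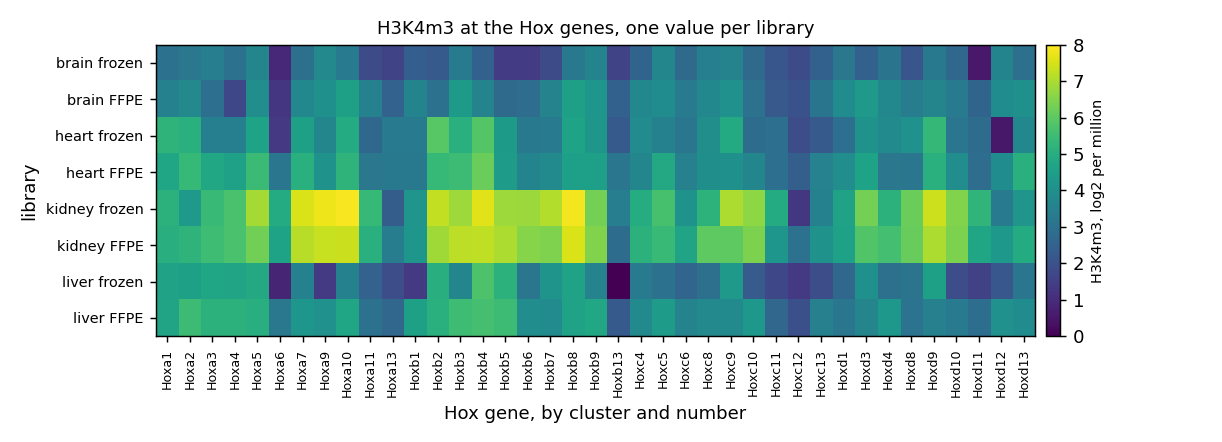
H3K4m3 at the 39 Hox genes (columns, by cluster and number) in each of the 8 libraries, as deposited log2 values on a colour scale from 0 to 8. Both kidney libraries are brightest over most of the 4 clusters and both brain libraries are dark, with list medians of 2.20 in kidney and -1.35 in brain relative to the other organs.

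Hox genes were higher in kidney for 27 of 39 members, 33 adjusted over the list alone, with a median of 2.20 (camera adjusted p = 1.64e-62, and adjusted p = 0.331 with an estimated correlation). The median was 2.76 among the frozen libraries and 1.90 among the FFPE libraries. Proximal tubule genes were higher for 6 of 16 members, 14 adjusted over the list alone, with a median of 1.33. They included the inositol-degrading enzyme Miox at 8.31-fold, the urate transporter Slc22a12 at 4.84-fold and Acsm2 at 2.6-fold (adjusted p = 0.331 with an estimated correlation). Genes of the loop, distal tubule and collecting duct were higher for 5 of 18 members, 10 adjusted over the list alone, with a median of 1.20. They included Fxyd2, a subunit of the sodium pump, at 8.22-fold, Umod, which encodes uromodulin, at 7.34-fold and the kidney cadherin Cdh16 at 4.48-fold (adjusted p = 0.331 with an estimated correlation). Podocyte genes and kidney transcription factors were higher for 4 of 13 members, 6 adjusted over the list alone, with a median of 0.60, among them Emx2 at 5.68-fold and Pax8 at 5.47-fold (adjusted p = 0.497 with an estimated correlation). Lower in kidney were Srrm4, a neural splicing regulator, at -2.13 ± 0.27, and the liver transcription factor Onecut1 at -1.74 ± 0.26. Onecut1 was high in liver, which is among the organs that kidney was set against.

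In kidney, 310 genes passed, 206 higher and 104 lower, and the 2 libraries did not overlap the others for 210. No overlap was found for 3.99% of tested genes, against 7.14% for exchangeable libraries, which these are not, so the value does not show a share below chance. The count was 0 without frozen kidney with limma, with 557 at an unadjusted p under 0.05, so that no gene named for kidney then passed. It was 167 without FFPE kidney, 133 without frozen brain, 128 without frozen heart, 205 without FFPE heart, 1033 without FFPE liver and 847 without frozen liver. It was 838 after quantile normalization, 201 without the filter and 527 with stretched libraries. With precision weights 204 genes were higher and 38 lower, a share of higher calls of 84.3% in place of 66.5%.

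Liver carried more H3K4m3 than the other organs at plasma protein genes, liver enzymes and liver transcription factors. Cyp8b1, an enzyme of bile acid synthesis (gene ID 13124, chromosome 9, 121914356 to 121916305), was 30.0-fold higher, at 4.91 ± 0.57 (SE, 2 liver and 6 other libraries, adjusted p = 0.000264). The acute-phase gene Crp was 28.8-fold higher. Apolipoprotein genes followed: Apoc3 was 23.7-fold higher, Apoa2 (gene ID 11807, chromosome 1, 171221564 to 171226379) 22.0-fold and Apoa5 20.3-fold higher. Onecut1, a hepatocyte transcription factor (gene ID 15379, chromosome 9, 74861921 to 74889648), was 7.69-fold higher, at 2.94 ± 0.26 with an adjusted p of 5.59e-05.

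Plasma protein genes were higher in liver for 26 of 28 members, 27 adjusted over the list alone, with a median of 2.58. Apoh, Fga, a fibrinogen chain, and the complement gene C3 were 12.5-fold, 8.15-fold and 5.03-fold higher (adjusted p = 0.475 with an estimated correlation). Liver enzymes and transporters were higher for 21 of 22 members, 22 adjusted over the list alone, with a median of 2.02. Hpd, an enzyme of tyrosine breakdown, was 8.68-fold higher (adjusted p = 0.497 with an estimated correlation). All 12 liver transcription factors were higher, 12 adjusted over the list alone, with a median of 2.23, led by Foxa2 at 11.1-fold and Foxa1 at 8.02-fold (adjusted p = 0.334 with an estimated correlation). Cytoplasmic ribosomal protein genes were higher for 14 of 73 members, 20 adjusted over the list alone, with a median of 0.43, among them Rpl27a at 1.9-fold (adjusted p = 0.566 with an estimated correlation). Neuron markers were lower for 6 of 20 members, 14 adjusted over the list alone, with a median of -0.82. Gria2 differed by -1.06 ± 0.23 (adjusted p = 0.52 with an estimated correlation). Hox genes were lower for 7 of 39 members, 8 adjusted over the list alone, with 1 higher, and a median of -0.69 (adjusted p = 0.566 with an estimated correlation). The other organs include kidney, where the Hox median was 2.20, and the brain median of -1.35 was lower than that of liver. The microRNA gene Mir744 had 0 reads in liver and 52 elsewhere, at least 5.77-fold lower, with 3 reads as the limit over the group.

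In liver, 2559 genes passed, 1317 higher and 1242 lower, and the 2 libraries did not overlap the others for 1471. No overlap was found for 9.56% of tested genes, against 7.14% for exchangeable libraries, which these are not. The count was 464 without frozen liver, 4832 without FFPE liver, 1435 without frozen brain, 1492 without frozen heart and 1499 without frozen kidney. Without frozen liver, Apoc3, Rpl27a and Mir744 no longer passed, and Gria2 did not pass without FFPE liver. With stretched libraries 979 were higher and 1557 lower, a share of higher calls of 38.6% in place of 51.5%, and with precision weights 1302 were higher and 695 lower, a share of 65.2%.

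Organ differences measured in frozen tissue were then set against those in FFPE tissue, which share no library. All 10 lists of genes typical of an organ stood above the other organs in both preservation types. The median of liver plasma protein genes was 3.54 in frozen and 1.71 in FFPE liver. That of neuron markers was 1.85 in frozen and 1.25 in FFPE brain, that of heart sarcomere genes 2.04 and 0.97, and that of proximal tubule genes 1.94 and 0.48. The FFPE median was smaller in all 10 lists, with a mean ratio of 0.456 ± 0.12 (SD over 10 lists). After quantile normalization it was smaller in 9 of the 10, with a mean ratio of 0.689 ± 0.182, and the ratio for neuron markers turned from 0.675 to 1.07. Across 25680 genes, Pearson's r between the frozen and FFPE organ contrast was 0.497 for brain, 0.241 for heart, 0.309 for kidney and 0.352 for liver, with Spearman's rho of 0.438, 0.269, 0.299 and 0.306. Genes are not independent replicates, and these values carry no p-value. Splitting the reads of each library at random put the highest r that counting noise allows at 0.822 for brain, 0.734 for heart, 0.72 for kidney and 0.828 for liver. The mean over organs was 0.35, and each frozen organ had its highest r with its own FFPE organ. Unmatched pairs lay between -0.295 and -0.011, since contrasts among 4 organs add up to 0. The matching had an exact one-sided permutation p of 0.0417, the smallest that 24 matchings allow. For levels, r was between 0.855 and 0.913 for the same organ across preservation types, between 0.842 and 0.897 for different frozen organs, and between 0.874 and 0.921 for different FFPE organs.

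**Figure D2:**
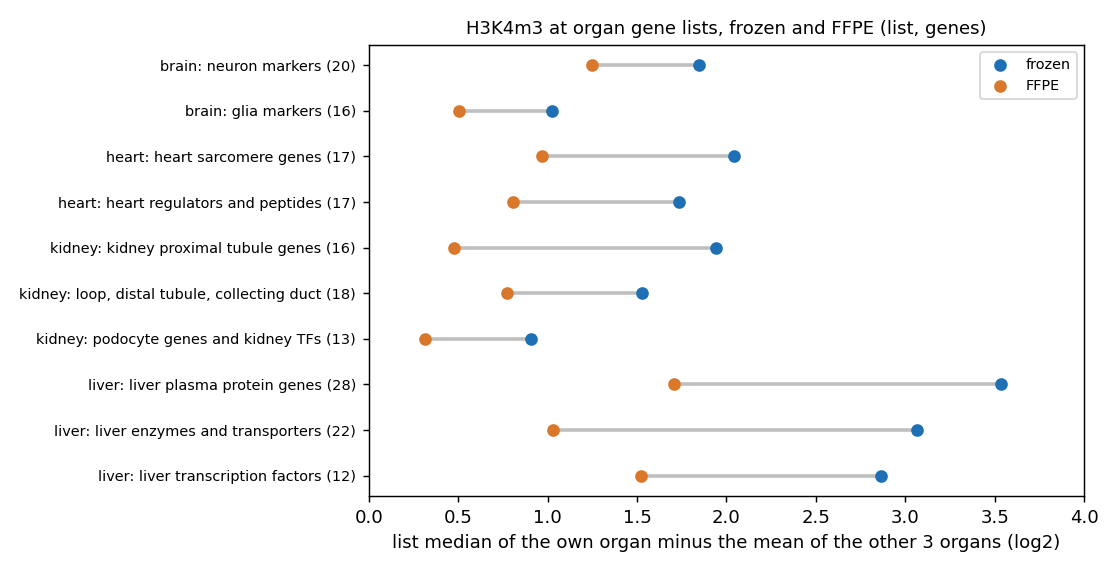
Medians of the 10 organ lists (number of genes in brackets) as log2 difference between the own organ and the mean of the other 3, in frozen (blue) and FFPE (orange) libraries. Every FFPE point lies to the left of its frozen point, from 1.71 against 3.54 for liver plasma protein genes to 0.31 against 0.91 for podocyte genes and kidney transcription factors, while after quantile normalization the FFPE to frozen ratio of neuron markers was 1.07.

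FFPE libraries had a smaller share of their reads than frozen libraries at cytoplasmic ribosomal protein genes. The genes with the largest increases included some that were almost without reads in frozen tissue. These are shares of reads compared without input libraries, so they do not measure the amount of H3K4m3 in the tissue. Srp54b, of the signal recognition particle (gene ID 665155, chromosome 12, 55155104 to 55189213), fell by 2.03 ± 0.19 on the log2 scale (SE, 4 FFPE and 4 frozen libraries, adjusted p = 8.6e-05). It has near-identical copies nearby, so its reads are uncertain. Sdhd, a subunit of respiratory complex II (gene ID 66925, chromosome 9, 50596340 to 50603849), fell by 1.84 ± 0.23. Both were lower in all 4 organs. Skint4, of a family that selects skin T cells (gene ID 320640, chromosome 4, 112072016 to 112168076), had 291 FFPE and 3 frozen reads, a ratio of 47.1 (95% counting interval 16 to 230). Vmn1r132 had 267 and 2 reads, a ratio of 64.8 (17.8 to 538). Vmn1r253 and Vmn1r151 had 0 frozen reads and were at least 21.0-fold and at least 18.3-fold higher, with 3 reads as the limit over the group. Trim12a, of an antiviral restriction factor family, was 23.5-fold higher and Nlrp1c-ps, a pseudogene of an inflammasome sensor, 22.6-fold higher. Vmn1r and Skint genes have close copies, so their reads are uncertain.

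**Figure D3:**
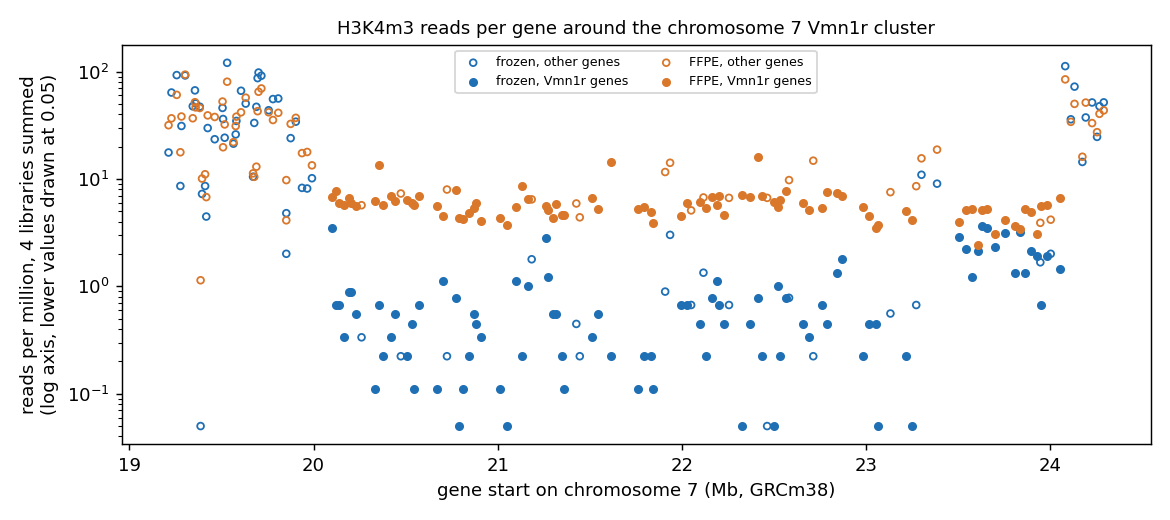
Reads of each gene around the chromosome 7 cluster of Vmn1r genes, scaled to library size and summed over 4 frozen (blue) or 4 FFPE (orange) libraries, on a log axis with values under 0.05 drawn at 0.05. The 66 Vmn1r genes between 20204684 and 23251682, a region chosen after the data were seen, held 296 frozen and 7368 FFPE reads.

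The median tested gene was 0.18 higher in FFPE with the deposited scaling, 0.003 with quantile normalization and 0.45 when scaled to reads outside the mitochondrial genome and Rn45s. List values are therefore also given relative to the median gene. Cytoplasmic ribosomal protein genes were lower for 54 of 73 members, 58 adjusted over the list alone, with a median of -0.77. Relative to the median gene this was -0.95, and -0.50 after quantile normalization (adjusted p = 0.566 with an estimated correlation). Rpl38 fell by 1.38 ± 0.17, Rps9 by 1.35 ± 0.16 and Rpl30 by 1.22 ± 0.15. Housekeeping genes were lower for 8 of 16 members and higher for 1, 11 and 1 adjusted over the list alone, at -0.65 relative to the median gene and -0.17 after quantile normalization (adjusted p = 0.566 with an estimated correlation). Polr2a was the 1 member that was higher, at 0.62 ± 0.17. Immediate early genes were lower for 13 of 19 members, 13 adjusted over the list alone, at -0.64 relative to the median gene but -0.02 after quantile normalization (adjusted p = 0.331 with an estimated correlation). Jun, Jund and Ier2 fell by 1.09 ± 0.17, 1.12 ± 0.17 and 1.06 ± 0.16, and did not pass with stretched libraries.

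Olfactory and vomeronasal receptor genes, which act in sensory neurons of the nose, were higher for 241 of 1448 members and lower for 1, 103 and 0 adjusted over the list alone. Their median of 0.76 did not change when the 2 genes without frozen reads were set at their limit. It was 0.58 relative to the median gene but turned to -0.09 after quantile normalization (adjusted p = 0.475 with an estimated correlation). Sarcomere genes were higher for 8 of 17 members and lower for 1, the same adjusted over the list alone, including the giant muscle protein gene Ttn at 0.79 ± 0.14. Relative to the median gene their median was 0.55, and 0.46 after quantile normalization (adjusted p = 0.584 with an estimated correlation). Immune markers were higher for 8 of 17 members, 9 adjusted over the list alone, among them Itgam at 2.1-fold and Ptprc at 1.7-fold, with 0.45 relative to the median gene and 0.39 after quantile normalization (adjusted p = 0.497 with an estimated correlation). Glia markers were higher for 6 of 16 members, 7 adjusted over the list alone, led by Mobp at 2.32-fold, with 0.40 relative to the median gene and 0.36 after quantile normalization (adjusted p = 0.61 with an estimated correlation). Other lists moved less evenly. Endothelial markers were higher for 4 of 12 members, 4 adjusted over the list alone, at 0.17 relative to the median gene and 0.59 after quantile normalization (adjusted p = 0.566 with an estimated correlation). Fibroblast and smooth muscle markers were higher for 3 of 12 members, 2 adjusted over the list alone, at 0.36 and 0.48 (adjusted p = 0.592 with an estimated correlation). Proximal tubule genes were higher for 4 of 16 members, 2 adjusted over the list alone, at 0.52 under both scalings (adjusted p = 0.585 with an estimated correlation). Genes of the loop, distal tubule and collecting duct were higher for 5 of 18 members, 2 adjusted over the list alone, at 0.47 and 0.16 (adjusted p = 0.566 with an estimated correlation). Hox genes were higher for 5 of 39 members, 3 adjusted over the list alone, at 0.36 and 0.17 (adjusted p = 0.585 with an estimated correlation). Neuron markers were higher for 4 of 20 members, 3 adjusted over the list alone, at 0.24 and 0.34, with a camera adjusted p of 0.0613. Heart regulators and peptides were higher for 3 of 17 members and lower for 1, at 0.32 and 0.21, with a camera adjusted p of 0.0719. Podocyte genes and kidney transcription factors were higher for 4 of 13 members and lower for 1, at 0.17 and 0.30. Their camera adjusted p was 0.0835, but 0.0281 after quantile normalization and 0.592 with an estimated correlation. No member of the 3 liver lists passed as higher with limma. Plasma protein genes had 1 of 28 lower, at 0.10 and 0.03 relative to the median gene, and enzymes and transporters stood at 0.01 and 0.03. Liver transcription factors had 2 of 12 lower, 2 adjusted over the list alone, and turned from -0.18 to 0.19 after quantile normalization. Red blood cell genes, 7 of 9 in the table, were higher for 3 and lower for 1, the same adjusted over the list alone. Their median of 0.67 relative to the median gene became -0.01 after quantile normalization, and their camera adjusted p was 0.111. Slc4a1, of the red cell membrane, was 2.29-fold higher, while the erythroid factor Klf1 fell by 0.74 ± 0.16 and did not pass after quantile normalization. Of 7 Y-linked genes, Uty passed as lower, at -0.66 ± 0.19, 1 adjusted over the list alone, with a list median of -0.55 relative to the median gene, -0.16 after quantile normalization, and a camera adjusted p of 0.75. Uty did not pass after quantile normalization. Under that scaling camera also no longer called the receptor list (adjusted p = 0.676), the immune list (0.144), the housekeeping list (0.128), the immediate early list (0.159), the Hox list (0.159) and the list of loop, distal tubule and collecting duct genes (0.235).

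**Figure D4:**
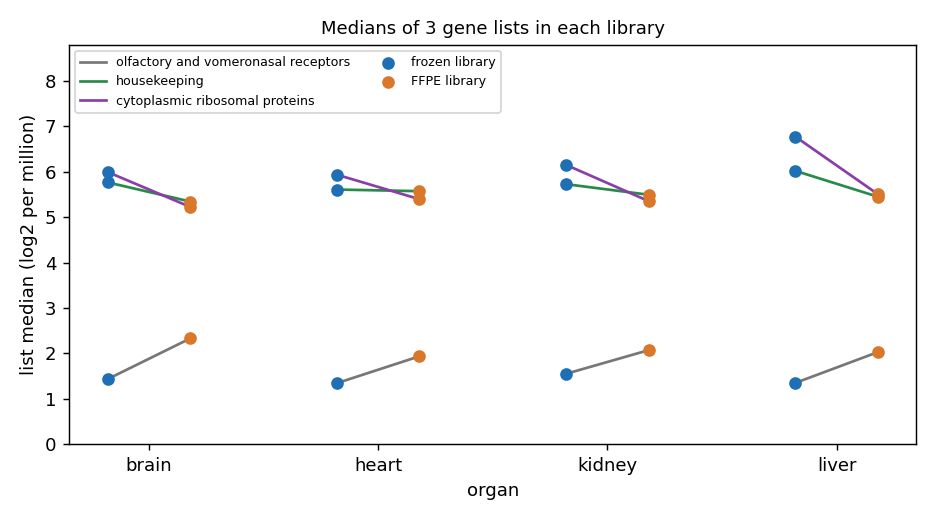
Median deposited log2 value of the receptor, housekeeping and ribosomal protein lists in each frozen (blue) and FFPE (orange) library. In all 4 organs the receptor median is higher and the other 2 medians are lower in FFPE as scaled by the authors, while relative to the median gene the receptor difference of 0.58 turned to -0.09 after quantile normalization.

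The distance between the housekeeping and the receptor median was 4.36 ± 0.216 in frozen and 3.37 ± 0.259 in FFPE libraries (SD, n = 4 each), smaller in FFPE in all 4 organs. Reads of the mitochondrial genome made up 3.62% ± 0.489 in frozen and 10.0% ± 5.54 in FFPE libraries (SD, n = 4 each), higher in FFPE in all 4 organs. With FFPE and frozen exchanged within organs, both had an exact two-sided permutation p of 0.125, which is the smallest that 4 organs allow and stayed 0.125 after adjustment over 5 such measures.

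In the comparison of FFPE with frozen, 9717 genes passed, 4240 higher and 5477 lower, and 9260 of these had the same sign in all 4 organs. The same sign in all organs was found for 53.3% of tested genes, against 12.5% for signs that are even and independent between organs. The scaling and depth that FFPE libraries share need not give such signs. With an absolute log2 fold change of at least 1, 2743 were higher and 1296 lower. After quantile normalization 3294 were higher and 3467 lower, 6761 in all, of which 4949 were among the 9717. Scaled to reads outside the mitochondrial genome and Rn45s, 7210 were higher and 3278 lower, a share of higher calls of 68.7% in place of 43.6%, and with stretched libraries 3958 were higher and 2155 lower. The count was 6063 without FFPE kidney and 6082 without frozen kidney. These are not separate checks: without either library of an organ, the other is fitted exactly and the FFPE difference is the same. Polr2a did not pass when either heart or either kidney library was left out, nor Ptprc without FFPE heart or FFPE kidney.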

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

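The values below were singled out after the data were seen, and none was tested for a cause. The median of cytoplasmic ribosomal protein genes in heart, relative to the other organs, was -0.323 among the frozen and 0.05 among the FFPE libraries, with opposite signs, and the difference was not tested. Reads of the mitochondrial genome, which carries no histones, made up 4.009% of reads in frozen and 6.163% in FFPE brain, 4.055% and 17.04% in heart, 3.332% and 11.81% in kidney, and 3.077% and 5.036% in liver. Of 14 groups checked with Dixon's test for a sample apart from the others, none held such a sample, where chance alone gives about 1 in 20 groups. With 8 libraries in all the groups were small, so the check had little power and does not show that the libraries are alike.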

How the results depend on the processing

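The precision weights, the scaling to reads outside the mitochondrial genome and Rn45s, and the stretched libraries were chosen after the data were seen. The other settings were chosen before. Of 2026 alternative values for 146 results on genes chosen by the rule for named genes, 1845 kept their direction and their side of the threshold, 181 kept the direction but no longer passed, and 0 reversed. For the largest differences, the rule took only genes that passed with all libraries and whose libraries did not overlap or shared their sign. Such genes can hardly reverse when a library is left out. The 0 was thus largely set by the choice of genes and adds no support. Losses were most frequent without frozen kidney (38), frozen heart (34) and frozen brain (21).

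In the organ comparisons, the number of genes that passed moved most when a library was left out. Its range over the 8 omissions was 326 to 4291 in brain against 2583 with all libraries, 2 to 2097 in heart against 661, 0 to 1033 in kidney against 310, and 464 to 4832 in liver against 2559. For FFPE against frozen it was 6063 to 8633 against 9717. In that comparison the 2 omissions of an organ test the same difference, so they are not separate checks. Leaving out a library leaves fewer residual degrees of freedom, which lowers power. Counts rose only where a liver library was left out. That omission takes liver's departure from an equal preservation difference out of the shared spread, but whether this accounts for the whole rise was not tested.

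Quantile normalization moved the count to 1382 in heart and 838 in kidney. It was 417 in heart with precision weights, and in kidney 201 without the filter and 527 with stretched libraries. The cause was not tested. An absolute log2 fold change of at least 1 left 1670 genes in liver and 4039 for FFPE against frozen, as fewer genes reach an added threshold. With stretched libraries the FFPE count was 6113, and the cause was not tested. With an estimated correlation, camera called 0 of the 100 pairs of gene list and comparison, with 12 at an unadjusted p under 0.05, against 58 with the preset correlation. The estimated setting tests on 3 residual degrees of freedom, so this change is not due to the correlation alone. The mean correlation between frozen and FFPE organ contrasts was 0.35, against 0.305 without the filter, 0.363 after quantile normalization and 0.349 with stretched libraries, each within its SD of 0.108. Other settings were not tried for it.

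No paired analysis was possible because the columns carry no replicate number, beyond the pairing by organ that the model already holds. A different pseudocount was not tried because the deposited values are already on the log2 scale. Settings that need input libraries, dates or separate FFPE replicates were not run, and the 4 FFPE columns alone leave no residual degrees of freedom. Depth limited the genes near 0 reads, of which the frozen libraries held 1105 to 1693 genes without any read and the FFPE libraries 341 to 672.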

Other observations

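Gene families of at least 10 members, 276 in all, were compared after the data were seen, with symbols as the only guide to membership. Camera called 91 of them between FFPE and frozen, 57 as lower, so the examples below stand for no tested theme. In FFPE tissue, 34 of 49 Mrpl and 23 of 29 Mrps genes of the mitochondrial ribosome passed as lower, as did 10 of 12 Ndufb genes of respiratory complex I, 17 of 27 Cox genes and 10 of 11 Tomm genes of the import pore. Families outside the mitochondrion were also lower, among them 9 of 11 proteasome genes (Psmb) with 1 higher, 13 of 18 Snhg noncoding RNA genes and 17 of 27 Arl genes. Higher were 14 of 15 axonemal dynein genes (Dnah), 25 of 44 collagen genes (Col), 12 of 14 mucin genes (Muc), 12 of 14 myosin heavy chain genes (Myh), and 21 of 54 keratin genes (Krt) with 1 lower. Relative to the median gene, each of these families kept its direction after quantile normalization and with stretched libraries, but the size depended on the scaling. After quantile normalization Tomm moved from -0.88 to -0.33, Mrpl from -1.02 to -0.62 and Krt from 0.76 to 0.31, while Dnah moved from 0.59 to 1.13. In liver, 19 of 23 major urinary protein genes (Mup, near-identical copies with uncertain reads), 16 of 26 Serpina genes, 12 of 21 Ugt genes and 40 of 104 Cyp genes passed as higher, with 1 Cyp gene lower. In brain, 8 of 17 synaptotagmin genes (Syt) were higher. With an estimated correlation camera called 0 of these families, with adjusted p-values of at least 0.834, again on 3 residual degrees of freedom. Across 24252 genes, Spearman's rho between the span of a gene and its FFPE difference was -0.148.

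The number of genes that passed between FFPE and frozen was set against other splits of the 8 libraries into 4 and 4 with organ in the model. The real split gave 9717 genes and was 1 of 32 splits that could be fitted. The highest other split gave 0 genes with limma, although up to 6376 genes had an unadjusted p under 0.05. In every other split some or all of the real FFPE difference counts as spread, which lowers the calls, so the 0 adds no support. Among the 8 splits that part all 4 organs, the smallest share possible is 0.125, so chance cannot be excluded by this count of splits alone.

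The smaller organ contrasts in FFPE, with a mean ratio of 0.456 to frozen over 10 lists, were examined for technical causes. Thinning every library to 1792394 reads left the ratio at 0.463. Each FFPE library was deeper than the frozen library of its organ, so thinning mainly cut FFPE reads. It could hardly have brought the ratio near 1, so the thinned value adds no support. Quantile normalization gave 0.689 ± 0.182 and stretching, which undoes a linear flattening of the log2 profile, gave 0.6 ± 0.21 (SD over lists). Each mean moved less than 0.5 of the way to 1. Stretched ratios ran from 0.268 for podocyte genes and kidney transcription factors to 0.938 for neuron markers, so the shortfall differed between lists. Reads from outside marked genes added to an otherwise equal profile would lower genes of the own organ no further than housekeeping genes. This holds only where own-organ genes stand no higher above background than housekeeping genes, which was not checked. The mean difference over all 10 lists was 0.135 ± 0.351 (SD), which leaves that explanation open. Parted by organ, it was 0.333 ± 0.171 over the 7 brain, heart and kidney lists and -0.326 ± 0.099 over the 3 liver lists. The SD is over lists that share the libraries of an organ, not over libraries. Added reads remain open for the first group. The liver value goes against the prediction, but it rests on 1 frozen and 1 FFPE library and on the unchecked premise. It does not settle the cause for liver.

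The predictions for these tests were written after the smaller contrasts had been seen. The parting into liver and the other lists, which gave 0.333 and -0.326, was made after the pooled value of 0.135 had been seen. The stretching test, with its value of 0.6, was first worded for a flatter profile caused by reads from outside marked genes, and was narrowed to a linear flattening after the values had been seen.

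The Vmn1r genes of chromosome 7 between 20204684 and 23251682 were noticed among the largest FFPE differences, with a median of 3.65 against 0.69 for Olfr genes and 0.88 for Vmn1r genes elsewhere, and the tests were chosen after that. Reads shared between near-identical copies were tested on 10 other families of copies, of which 0 lay at least 1 above the Olfr median, against 2.96 for the cluster, which argues against copies as the main cause. Of the 10, 8 lay above the Olfr median, Obox highest by 0.981, so a smaller part played by copies is not excluded. Lower depth and background in frozen tissue would give 2181 frozen reads over the cluster (Poisson 95% interval 2090 to 2273), and 296 were found, a prediction worded after the values had been seen. A difference in strain or animals between the frozen and the FFPE tissue could also give such a gap at 296 reads, was not tested, and remains open because the labels name no strain.

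The gap was not confined to this cluster. At most 2 frozen and at least 30 FFPE reads were found for 134 genes, of which 27 lay in the cluster, and the opposite was found for 0 genes, with more reads in every FFPE library than in the frozen library of its organ. Of 28 Defa genes, which encode defensins, 9 had at most 2 frozen reads, with 193 frozen and 1044 FFPE reads in all.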
